A study of Petromyzon marinus with 21 samples.

How the data were processed

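RNA of whole sea lamprey embryos (Petromyzon marinus, a jawless vertebrate) and of adult testes was counted on the NanoString nCounter, which hybridises a barcoded probe to each chosen transcript and counts the barcodes without amplification. Per the labels, 6 ages of embryo between 1 and 5 days after fertilization (D1, D2, D2.5, D3, D4 and D5, named for the day) were taken, each in 3 biological samples, and the 3 testes samples were technical replicates, which were therefore treated as 1 biological sample. The file headers name 63 probes in 4 classes: 43 target probes (class endogenous), 6 reference probes (class housekeeping), 6 positive controls and 8 negative controls. Of the 43 target probes, 24 carry no annotation in the file and 19 carry a gene name. The reference class holds RPS9, EF1A_A and EF1A_B (ribosomal protein S9 and 2 probes of elongation factor 1 alpha), HCFC-1, Piwi-1 and Piwi-2.

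The raw counts were used as deposited, whole numbers with no zero and a lowest count of 1, per the file headers and the values. The authors also deposited a table of normalized signal values. Over the 17 lanes whose column names 1 sample, all of 833 such values (100%) were recovered within 2% from the raw counts by subtracting the geometric mean of the negative controls, setting results at or below 0 to 1, scaling each lane to 1 common sum of EF1A_A and EF1A_B, and setting scaled values under 1 to 1. That recipe was inferred from the values, and the order of the floors was chosen because it matched them best; software and settings used by the authors are not given in the sources used here. The deposited signal values entered only as an alternative.

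The column names of 17 lanes give a stage and a replicate number. The other 4 lanes (2 of D4, 2 of D5) give a stage only and are called a and b here, with no order. The names also show 3 runs of the instrument: D1 to D3 (12 lanes), D4 and D5 (6 lanes), and testes (3 lanes). D2 vs D1, D2.5 vs D2, D3 vs D2.5 and D5 vs D4 lay within a run, and the other comparisons could not be separated from the run.

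Each lane's background was the mean + 2 SD of its 8 negative controls. A target probe was tested if above background in at least 3 of the 18 embryo lanes, which left 38 of 43. Lanes were scaled by the geometric mean of the positive controls and then by that of the reference probes above background in every lane compared. For the embryos these were EF1A_A and HCFC-1. For the 21 lanes with testes it was HCFC-1 alone. The reference step cancels the positive controls, so the alternative without them was identical by construction. A scaled count is a count divided by the lane's factor, with a mean factor of 1. Among the alternative scalings, TMM and DESeq2's size factors were computed from the 38 tested probes, and the sum from all 43 target probes. They tie the level of a lane to the target probes themselves. A change shared by most of the panel is then taken out in whole or in part by construction.

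The embryo lanes were fitted with edgeR 4.0.16 (quasi-likelihood, robust, stage as the factor, R 4.3.3), with Benjamini-Hochberg adjustment over the 38 probes and a threshold of 0.05. The standard error of a log2 fold change was taken as its size over the square root of the F value. Tests were two-sided. limma 3.58.1 served for log2(scaled count + 1) and for the rotation test fry, and DESeq2 1.42.0 as an alternative; an adjusted p named for edgeR, limma or DESeq2 is from these fits. A probe below background in every lane of a stage entered a fold at that stage's mean background, and the fold is then a lower bound. The panel level of a lane is the mean of log2(scaled count + 1) over the 38 probes; its permutation tests used 100000 resamples, or all 816 combinations where the 3 D1 lanes were set against the 15 later ones. Replicate numbers were checked as pairs by correlating the deviations of same-number lanes from their stage means over the 38 probes, with all pairs over 0.1 as the rule. Of 6 stage pairs in the first run, D2.5 with D3 met it (0.173 to 0.794), which comes from the values, not the labels. Testes were compared by a rule of size, at least 4-fold above the highest or below the lowest stage mean.

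The edgeR fit was tested on simulated counts for D5 vs D1, in 20 panels of 38 probes with 5 changed probes each. At the dispersion of these lanes, 0.910, it recovered 4% of 100 probes changed 4-fold, 45% of 100 changed 16-fold and 97% of 100 changed 64-fold, with 0%, 0.303% and 0.758% of unchanged probes called. At a dispersion of 0.1 it recovered 96% of the 4-fold changes. With probes drawn independently and no stage effect, no more than 1 probe was called for D5 vs D1 in any of 100 panels. In all of these panels the unchanged level of a probe was its mean over the 18 embryo lanes. For most of the probes called in the data this lies above their D1 counts. The recovered shares therefore do not give the power at D1 levels.

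The total of the target counts lay between 504 and 15415 per embryo lane and between 450972 and 473907 per testes lane. The comparisons of successive stages, of D5 with D1 and of testes, the rule for scaling and the lists were fixed before the data were examined. That rule named reference probes above background in every lane, and reading it per comparison was settled once the values were seen; HCFC-1 alone, which the rule gives over all 21 lanes, and EF1A_A alone were added as scalings for the embryos. The comparison of D1 with all later lanes was also added then. Named probes were, for D5 vs D1, up to 12 rises and 12 falls with adjusted p under the threshold and above background in every lane of the higher stage, up to 4 each way for successive stages, up to 10 highest and 10 lowest in testes, up to 4 members of each list with the largest change from D1 to D5, and the 5 with the smallest range over the stages. Of the lists, the target class, meiosis and DNA repair, muscle with heart and blood, WNT signalling, and cell adhesion with matrix had members on the panel, matched by the annotation in the file; only the target class had the 3 tested members needed for a list test. Reference-class probes outside the scaling were tested together with the target probes as an addition made after the data were seen. Alternatives were other scalings, no filter on low probes, background subtraction, other tests, the deposited signal values, a replicate block, fewer stages, and each lane left out in turn. The reference table of gene names held none of the file's identifiers, and no genome was used, so no coordinates are given.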

Results

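The series measured 43 target transcripts in 18 samples of whole sea lamprey embryos over the first 5 days of development and in 1 adult testes sample read in 3 technical lanes. Per the labels it asks how expression changes between developmental time points and in adult testes. Somatic cells of the sea lamprey lose part of the germline genome during early embryogenesis; the labels do not say whether the transcripts were chosen for that reason. Testes lanes held far more target signal than any embryo lane, with 450972 to 473907 target counts against 504 to 15415. Counts of the 3 testes lanes differed by no more than sampling noise, with a chi-square per degree of freedom between 0.890 and 1.28. Every pair of lanes within an embryo stage differed by more, with at least 2.73.

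Few of the target transcripts were detectable in the youngest embryos. At D1, 3 of the 43 target probes were above background in all 3 lanes: aspartate aminotransferase (comp293586, an enzyme of amino acid metabolism), a synaptonemal complex protein 1 probe (comp292635_9; SYCP1 joins paired chromosomes in meiosis) and the unannotated comp292169. The number above background in all 3 lanes was 3 at D2, 15 at D2.5, 25 at D3, 11 at D4 and 10 at D5, and 42 in testes. Lanes of a stage differed widely, between 15 and 40 probes at D2.5 and between 10 and 40 at D5. The background differed as well, with a mean of 22.9 scaled counts at D1, 8.72 at D2.5 and 19.3 at D4. D2.5 replicate 1 and D4 replicate 1 had similar panel levels, 4.12 and 4.03. They had 34 and 11 probes above backgrounds of 7.78 and 23.2 raw counts. These numbers therefore depend on the background of a lane as well as on its target level. Counting probes above background in at least 2 of 3 lanes gave 6, 18, 34, 37, 36 and 38 over the 6 stages.

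**Figure D1:**
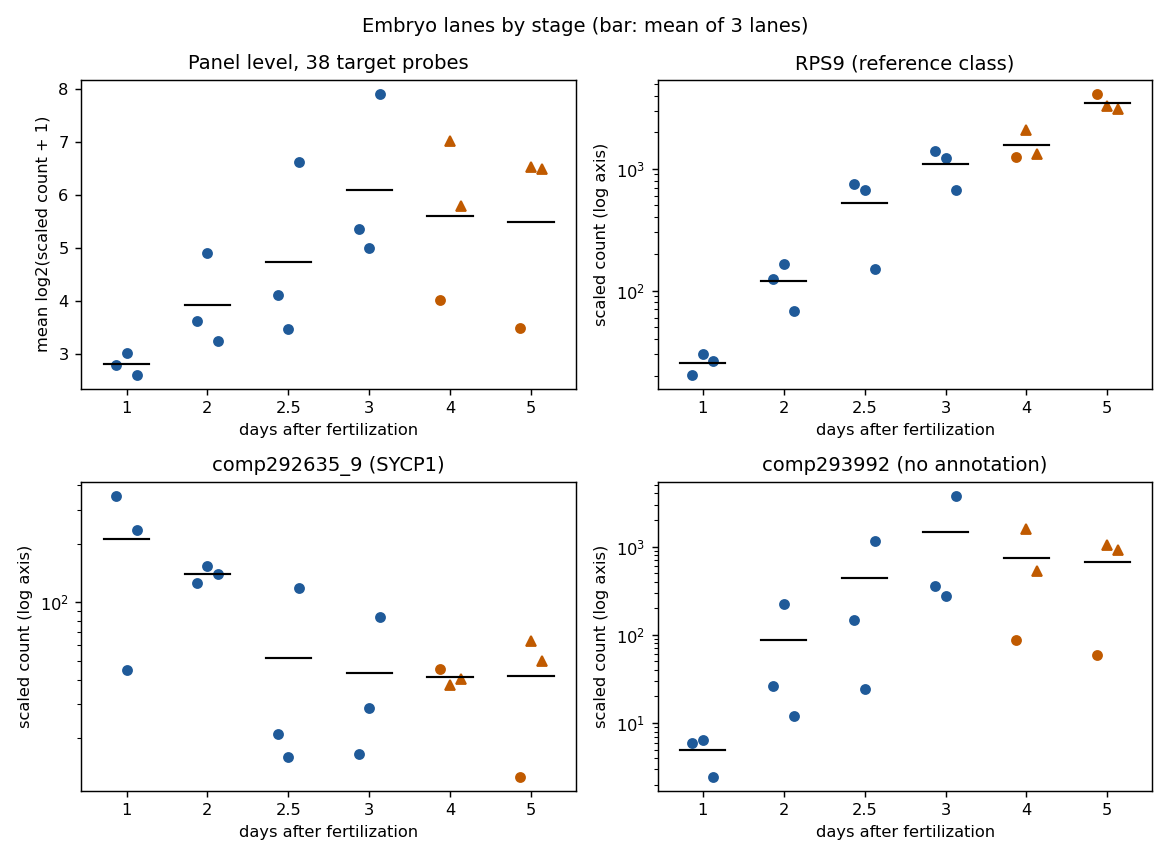
Each point is 1 of 18 embryo lanes, plotted by day after fertilization (bar, mean of 3 lanes); blue marks the run of D1 to D3, orange the run of D4 and D5, circles lanes with a replicate number and triangles the 4 without. The panel level (mean log2 of scaled count + 1 over 38 target probes) of the 3 D1 lanes is below that of the other 15 on this scaling but not with positive controls only, the sum of the target probes, HCFC-1 alone, TMM or DESeq2 size factors, RPS9 rises from 25.5 at D1 to 3500 at D5, and comp292635_9 and comp293992 are plotted as scaled counts on log axes.

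The 3 D1 embryo lanes had the lowest levels of the target panel of all 18 lanes on this scaling and with EF1A_A alone (rank sum 6). They were not the 3 lowest with positive controls only (rank sum 8), the sum of the target probes (9), HCFC-1 alone (10), TMM (40) or DESeq2's size factors (38). The sum, TMM and DESeq2's size factors are set by the target probes, so they remove or reduce a low level shared by the panel. The mean panel level was 2.82 ± 0.21 on the log2 scale at D1 (SD, n = 3) and 5.18 over the 15 later lanes, a difference of 2.36 (exact permutation test over 816 combinations, two-sided, p = 0.0123); this grouping was chosen after the stage values were seen. The stage means were 3.93 ± 0.87 at D2, 4.74 ± 1.66 at D2.5, 6.09 ± 1.58 at D3, 5.62 ± 1.51 at D4 and 5.51 ± 1.75 at D5 (SD, n = 3 each). Over all 6 stages the permutation test gave p = 0.107, so a difference between stages beyond the spread between lanes was not shown. The scaling changed that permutation p, to 0.0259 with the sum of the target probes and 0.0462 with EF1A_A alone.

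Between the first and the last stage, 24 of the 38 tested transcripts rose and 1 fell (edgeR), whereas TMM gave 2 rises and 10 falls, DESeq2's size factors 7 rises and 10 falls, and HCFC-1 alone 19 rises and 0 falls. TMM and DESeq2's size factors are set by the tested probes themselves, so a rise shared by most of them would also appear there as a mix. D1 was read in the first run and D5 in the second, so this comparison could not be separated from the run. Of the 10 splits of these 6 lanes, the real one included, 2 gave 25 or more calls, with 27 as the highest of the others. The largest rises among transcripts above background in all 3 D5 lanes were those of the unannotated comp293992 and comp292315, both below background in every D1 lane. Their D5 levels were 673 ± 537 and 585 ± 463 scaled counts (SD, n = 3), at least 29.4-fold and 25.6-fold above the D1 background of 22.9. A baculoviral IAP repeat-containing protein 1 probe (comp285297_12, of a family of apoptosis inhibitors) was at least 16.4-fold higher, and comp293931 and comp293924 were at least 11.3-fold and 8.56-fold higher. The other probe with the baculoviral IAP annotation, comp285297, did not pass (edgeR log2 fold change 2.73, adjusted p = 0.0680), with a lower bound of 1.16-fold. comp292169, measured in all D1 lanes, had a mean 9.05-fold higher, at 45.8 ± 11.03 and 414 ± 334 scaled counts, although its log2 fold change was −1.06 with TMM and −0.80 with DESeq2's size factors. These D5 means rest on the unnumbered lanes a and b, whose names share a tag that the labels do not explain. For comp292169 the numbered D5 lane had 37.4 scaled counts, under the D1 mean, against 674 and 531 in lanes a and b. Its log2 fold change in the 14 numbered lanes was −0.29. For comp293931 and comp293924 the numbered lane had 17.9 and 17.2, under the D1 background, against 361 and 396, and 309 and 262. For comp285297_12 it had 37.4 against 573 and 515, and for comp293992 and comp292315 58.3 and 59.0 against at least 917 and 767. The transcript that fell was comp292635_9, the SYCP1 probe, 5.03-fold from 211 ± 155 to 41.9 ± 26.1 scaled counts.

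The edgeR log2 fold changes from D1 to D5 were 7.09 (SE 2.05, adjusted p = 0.0028) for comp293992, 6.40 (SE 1.89, adjusted p = 0.0032) for comp292315 and 5.22 (SE 1.68, adjusted p = 0.0058) for comp285297_12. For comp293924 and comp293931 they were 5.98 (SE 1.56) and 5.33 (SE 1.46), each with adjusted p = 0.0028 in edgeR. Those of comp292169 and comp292635_9 were 3.18 (SE 1.46, adjusted p = 0.0451) and −2.33 (SE 1.02, adjusted p = 0.0397) in edgeR. The call of comp292169 ended without D1 replicate 1, 2 or 3 (edgeR adjusted p = 0.127, 0.0803 and 0.147) and without D5 lane a or b (0.139 and 0.105). It also ended in edgeR with the sum of the target probes (log2 fold change 1.03, adjusted p = 0.241), no filter (0.0545), the negative control mean subtracted (0.0552), the reference-class probes tested as well (0.0588), HCFC-1 alone (0.0821) and without the 3 lanes with the fewest EF1A_A counts (0.0949). In limma it ended on scaled counts (adjusted p = 0.122) and on the deposited signal values (0.0666). That of comp292635_9 ended without D1 replicate 1 or 3 (edgeR adjusted p = 0.143 and 0.0683), D5 replicate 1 (0.108), or D5 lane a or b (0.104 and 0.149). It also ended in edgeR with no filter (0.0700), the negative control mean subtracted (0.0521), only the 2 stages compared (0.0830), EF1A_A alone (0.0546) and HCFC-1 alone (0.0522). In limma that fall did not pass on scaled counts (adjusted p = 0.0842) or on the deposited signal values (0.0823, and 0.0577 with the number as a block). The target class as a whole moved upward in limma's rotation test fry (adjusted p = 0.0374 for direction, with 1 list tested, and 0.0175 for change either way). That call ended without D1 replicate 1, 2 or 3 (0.0712, 0.0630 and 0.0797), without D5 lane a or b (0.123 and 0.121), and with TMM (0.119). The count adjusted over the list alone is the same 24 and 1, since the list is the tested panel, which the study chose. DESeq2 called all of the 25 and limma 15 of them. The median log2 fold change of the panel was 3.50 on this scaling, −0.46 with TMM and −0.17 with DESeq2's size factors. The last 2 medians lie near 0 by construction, since those factors come from the same probes. They cannot show whether the panel as a whole rose. The 14 lanes with a replicate number, which include 1 D5 lane, gave 0 calls, and the count was 14 without D1 replicate 1, 13 without D1 replicate 3 and 16 without D5 lane a.

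Over all 6 stages at once, 20 of the 38 transcripts passed the edgeR test (all of them among the 25 above), against 6 with TMM, 9 with DESeq2's size factors and 0 with the negative control mean subtracted. Random regroupings of the lanes gave 20 or more in 8 of 100 splits, the real one included, so chance cannot be excluded. The lowest values were those of comp293931 and comp293924 (edgeR adjusted p = 0.0084 each). Their means were highest at D3, at 342 ± 421 and 407 ± 444 scaled counts (SD, n = 3), with 1 D3 lane far above the others. WNT-5a (comp249676, a secreted signalling protein) had means of 2.10 ± 1.89 at D1, 87.8 ± 99.5 at D3 and 33.5 ± 28.7 at D5, with adjusted p = 0.0143 in edgeR over the stages. The germ-cell helicase HFM1 (comp293440, which acts in meiotic crossing over) had 1.39 ± 0.68, 37.4 ± 42.9 and 22.6 ± 17.6, also with adjusted p = 0.0143 in edgeR. Both were below background in every D1 lane (mean background 22.9), and the D5 mean of HFM1 lies under that level, so no fold from D1 to D5 is given for it. limma called 8 over the stages and the number at an unadjusted p under 0.05 was 24 in edgeR. The number of edgeR calls was 0 without D1 replicate 1, 4 without D1 replicate 2 and 0 without D1 replicate 3.

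No target transcript passed the test between successive stages (edgeR). Most fold changes were positive up to D3, in 34 of 38 transcripts for D2 vs D1, 35 for D2.5 vs D2 and 36 for D3 vs D2.5, with medians of 1.45, 1.52 and 1.43 on the log2 scale. The step from D2 to D2.5 rested on D2.5 replicate 3, with a panel level of 6.62. The other D2.5 lanes had 4.12 and 3.48, against a mean of 3.93 ± 0.87 at D2 (SD, n = 3). From D3 to D4 all 38 were negative with a median of −0.65, and from D4 to D5 12 were positive with a median of −0.13. At an unadjusted p under 0.05, edgeR gave 8 transcripts for D2 vs D1, all higher at D2, and 0 for each of the other steps. DESeq2 called 2 for D2 vs D1 and 1 for D5 vs D4, and limma 0 for each step. The lowest adjusted p in edgeR for D2 vs D1 was 0.0756, but other settings called some. TMM called 7 higher and 3 lower (median −0.16), DESeq2's size factors 4 and 5 (−0.56), and the sum of the target probes 9 and 1 (1.06). The number was 8 with only the 2 stages fitted, 7 with the negative control mean subtracted, and 12, of which 11 were higher, with the replicate number as a block on the D1 and D2 lanes, which it did not pair. Without D2.5 replicate 3 edgeR called 2 transcripts for D3 vs D2.5 and 1 for D2 vs D1, and without D3 replicate 3 or D5 replicate 1 it called 1 for D2 vs D1. With the replicate number as a block on the D2.5 and D3 lanes alone, an addition made after the data were seen, 35 transcripts rose for D3 vs D2.5 (edgeR), 35 with EF1A_A alone and 33 with HCFC-1 alone. Positive controls only gave 1 rise (median log2 fold change 1.08, 35 of 38 positive) and the sum of the target probes 0 (0.45, 31 positive, 8 at an unadjusted p under 0.05). TMM gave 0 rises and 3 falls (−0.15, 9 positive) and DESeq2's size factors 0 rises and 3 falls (0.049, 21 positive). The panel level was higher at D3 in 3 of 3 pairs of 1 number, by 1.36 ± 0.15 on the log2 scale (SD, n = 3 pairs; exact permutation test, two-sided, p = 0.25, the smallest that 3 pairs can give), and whether the numbers pair these lanes stays open. The step from D3 to D4 could not be separated from the change of run.

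Aspartate aminotransferase (comp293586) had the smallest range over the stages, 1.03 on the log2 scale between the lowest and highest stage, with 1135 ± 407 scaled counts at D1 and 1567 ± 193 at D5 (SD, n = 3). The edgeR log2 fold change from D1 to D5 was 0.47 (SE 1.75, adjusted p = 0.812), and −2.06 with TMM. A MAD2L1-binding protein probe (comp280581, of the spindle checkpoint) gave 55.4 ± 26.4 and 134 ± 19.4, and the cordon-bleu probe comp287546 gave 7.92 ± 4.27 and 19.5 ± 12.6; with TMM their log2 fold changes were −1.35 and −2.21, the second past the threshold (edgeR adjusted p = 0.0148), whereas comp287546 passed as a rise with the negative control mean subtracted (6.71, edgeR adjusted p = 0.0370). comp287546 was below background in every D1 lane and above it in 1 of 3 D5 lanes, so its range and changes lie near the floor. The other cordon-bleu probe, comp266794, was among the rises from D1 to D5 (edgeR log2 fold change 4.82, adjusted p = 0.0058). It was below background in every D1 lane and had 49.2 ± 38.3 scaled counts at D5, with 5.23 in the numbered D5 lane. Of the lists fixed in advance, meiosis and DNA repair had 2 tested members, both SYCP1 probes: comp292635_9 fell and comp292635 did not pass, at 33.6 ± 29.4 and 35.0 ± 27.8. The latter passed as a fall in edgeR with TMM (−4.35, adjusted p = 5.3e-05), DESeq2's size factors (−4.12, adjusted p = 9.2e-05) and the sum of the target probes (−1.81, adjusted p = 0.0089). Cell adhesion had 1, protocadherin FAT3 (comp284391), at 13.8 ± 9.36 and 19.5 ± 13.5 with adjusted p = 0.722 in edgeR, but it passed as a fall with TMM (−3.31, edgeR adjusted p = 0.0062) and DESeq2's size factors (−3.06, edgeR adjusted p = 0.0137). FAT3 was below background in every D1 lane (mean background 22.9 scaled counts), so a fall from D1 cannot be shown for it. WNT signalling had WNT-5a (comp249676), at least 1.47-fold higher at D5 (adjusted p = 0.0158 in edgeR), with a log2 fold change of −0.0099 with TMM. Its numbered D5 lane had 1.49 scaled counts, under the D1 mean of 2.10, against 56.8 and 42.3 in lanes a and b. In the 14 numbered lanes the log2 fold change was −0.29. That call ended without D1 replicate 1 or 3 (edgeR adjusted p = 0.0778 and 0.0829), without D5 lane a (0.0658), with DESeq2's size factors (0.743) and in limma (0.0842). The muscle list had myosin-7B (comp292635_13), below background in every embryo lane and not tested. Its name is that of the file, and its identifier shares the stem comp292635 with the 2 tested SYCP1 probes. What that stem means is not given in the file.

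Among the reference probes, RPS9, a protein of the small ribosomal subunit, rose over development. Its scaled count was 25.5 ± 4.81 at D1, 119 ± 49.1 at D2, 528 ± 329 at D2.5, 1100 ± 376 at D3, 1562 ± 458 at D4 and 3500 ± 549 at D5 (SD, n = 3 each). The edgeR log2 fold change from D1 to D5 was 7.09 (SE 0.69, adjusted p = 2.6e-08 over 42 probes) and stayed at or above 4.74 under the other scalings tried. RPS9 also rose from D1 to D2 (2.22, SE 0.56, adjusted p = 0.025 in edgeR) and from D2 to D2.5 (2.15, SE 0.55, adjusted p = 0.0309 in edgeR). In limma neither of these steps passed (adjusted p = 0.234 and 0.774), while the change from D1 to D5 did (adjusted p = 9.0e-07). D2.5 replicate 3 had 152 scaled counts of RPS9, within the D2 range of 67.3 to 165. Piwi-2 and Piwi-1, of the family that silences transposons in germ cells, had 57.0 ± 15.4 and 42.4 ± 14.3 scaled counts at D1 and 18.9 ± 4.76 and 26.4 ± 3.14 at D5. At D3 they had 13.6 ± 7.51 and 7.94 ± 2.87, and at D4 8.94 ± 2.29 and 6.85 ± 4.72, with no lane above background at either stage. Over the 6 stages neither passed in edgeR (adjusted p = 0.0652 and 0.0777). In limma Piwi-2 did not pass either (adjusted p = 0.0574), but Piwi-1 did (adjusted p = 0.0497). From D1 to D5 neither passed in edgeR (log2 fold changes −1.58 and −0.68, adjusted p = 0.114 and 0.449), nor with positive controls only, EF1A_A alone or HCFC-1 alone. Both passed as falls in edgeR with TMM (−4.73 and −3.46, adjusted p = 0.0015 and 0.0228), DESeq2's size factors (−4.49 and −3.25, adjusted p = 0.0021 and 0.0241) and the sum of the target probes (−3.30 and −2.11, adjusted p = 2.5e-05 and 0.0040). On these 3 scalings a rise shared by the target probes lowers every other probe, so those falls cannot be told from a rise of the panel. The median log2 fold changes of the panel were −0.46, −0.17 and 1.70 there, above both Piwi probes each time. EF1A_B reached at most 8 counts in embryos.

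In adult testes, 38 of the 43 target transcripts were at least 4-fold above the highest embryo stage mean and 0 were 4-fold below the lowest, while TMM, DESeq2's size factors and the sum of the target probes gave 0 above and 5, 6 and 5 below. HFM1 was 41.4-fold above its D3 mean, with 5903 ± 102 raw counts in testes (SD, n = 3 technical lanes) against at most 77 in any embryo lane. The cordon-bleu probe comp287546 was 31.3-fold higher, and the unannotated comp293073_4, comp279056, comp289786, comp293931, comp290695, comp274039 and comp30676 were 23.5-fold to 28.9-fold higher. Myosin-7B was at least 27.5-fold higher, with 1720 ± 35.8 counts in testes and at most 7 in embryos. The 3 SYCP1 probes differed: comp292635 was 22.2-fold and comp288706 at least 8.50-fold above the highest stage, while comp292635_9 had 0.290 of its D1 level. Aspartate aminotransferase had 0.336 of its lowest stage mean on this scaling and 3.25 of it in the authors' deposited signal values.

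The testes comparison has no replicate check, since testes were 1 sample, and it could not be separated from the run. Its scaling rests on HCFC-1, which had 172 ± 5.00 counts in testes (SD, n = 3 technical lanes), barely above a background of 127 to 136. EF1A_A, the brighter reference in embryos, had 17.7 ± 5.13 counts in testes, below background, and EF1A_B had 206 ± 30.7. Positive controls alone gave 41 of 43 transcripts; the scalings that gave 0 tie the level of a lane to the target probes themselves. Among the reference probes, Piwi-1 had 555 ± 30.3 counts in testes and at most 49 in embryos, while Piwi-2, at 106 ± 9.07, was below the testes background.

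**Figure D2:**
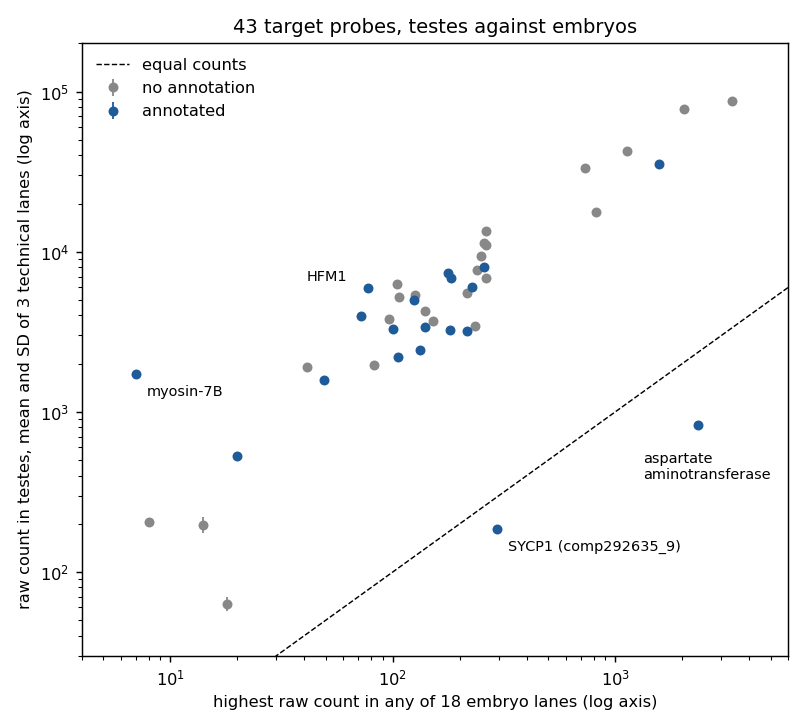
Raw count of each of the 43 target probes in testes (mean and SD of 3 technical lanes, log axis) against its highest raw count in any of 18 embryo lanes (log axis); blue probes carry an annotation, grey ones none, and the dashed line marks equal counts. All but 2 of the probes, aspartate aminotransferase and the SYCP1 probe comp292635_9, sit above the line.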

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

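The tests of testes RNA, amount of RNA, stage, and swapped labels, with their limits, were chosen after the values were seen, and the simulated panels and the matchings of lanes too; the counts of regroupings were planned. Some are replacements made after an earlier form had given its result. For testes RNA, the first form used D3 replicate 3 alone and argued against that source, and the second counted probes with an upper limit under 0.276% and left it undecided at 2 of 37. For the amount of RNA, the first form used D2.5 replicate 3 alone. Negative control probes, which match no transcript, averaged 61.5 counts in the testes lanes and between 3 and 8.13 in the embryo lanes, a signal in data outside the comparisons. Groups of 3 lanes were too small for a test of single outlying samples.

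The panel level of the target probes differed between lanes of 1 stage by an SD of 1.38 on the log2 scale. RNA of this testes sample as the whole source would bring the same percent of its testes count to every probe. In the summed embryo lanes that percent had a median of 0.553 over 37 probes abundant in testes, but 31 of the 37 differed from it beyond their 95% counting limits, and myosin-7B had 34 counts where 265 were needed. These values argue only against testes RNA as the whole source. A partial contribution was not tested, and summed lanes cannot show what differs between lanes. The amount of RNA was examined on raw counts, where the panel level had an SD of 1.37 within stages. There the EF1A_A count of the lane removed 26.9% of the variance within stages (bootstrap 95% limits −3.82 to 48.3). That argues only narrowly against the amount of RNA as the source of most of the raw spread, as the upper limit lies just under the 50% set for that. The scaled panel level is already scaled by EF1A_A and HCFC-1. Developmental stage stays open, because the permutation test gave p = 0.107 with stage means up to 3.28 apart; RNA from another source was not tested.

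D2.5 replicate 3 stood apart from its siblings in RPS9, at 152 scaled counts against 758 and 676, and in comp292635_9, at 119 against 21.1 and 16.1. A swap with a D2 lane would need a D2 lane out of place, but the highest D2 lane in RPS9 had 165. Its EF1A_A count argued against a low amount of RNA, at 1.04 times the mean of the other D2.5 lanes. Its RPS9 lay below both siblings on every scaling tried, but its comp292635_9 did not lie above them with TMM (63.2 against 81.9 and 104) or DESeq2's size factors (56.7 against 70.3 and 86.3). A single wrong label and embryos behind in development stay open, though its panel level of 6.62, against 4.12 and 3.48 in its siblings and at most 4.91 at D2, runs opposite to the stage means of D1 to D3. That level lay below both siblings with TMM (5.73 against 5.97 and 5.99) and DESeq2's size factors (5.58 against 5.76 and 5.73), and above them on the other scalings tried. D3 replicate 3 differed from its siblings in the same directions on this scaling. It had 675 against 1391 and 1233 in RPS9, 84.4 against 16.6 and 28.4 in comp292635_9, and a panel level of 7.91 against 5.37 and 5.00.

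Regrouping the 18 embryo lanes at random gave as many changed probes over 6 groups as the real stages, 20, in 8 of 100 splits, with 32 as the highest of the others, so chance cannot be excluded for that count. For D5 vs D1, 2 of the 10 splits of the 6 lanes gave as many as the real 25 calls, with 27 as the highest of the others; 10 splits are too few for a share under 0.05. The same holds for D2 vs D1, D2.5 vs D2, D4 vs D3 and D5 vs D4, where the real split and the highest of the others gave 0 and all 10 splits count as equal. For D3 vs D2.5 the real split gave 0 and another gave 32, again of 10 splits; that many calls point to a structure of the samples, whose origin was not tested. That split set D2.5 replicates 1 and 2 and D3 replicate 2, with panel levels of 4.12, 3.48 and 5.00, against D2.5 replicate 3 and D3 replicates 1 and 3, with 6.62, 5.37 and 7.91. With the replicate block on these lanes, the real split gave 35 calls and each of the other 3 splits that part all pairs gave 0. Simulated panels with no stage effect but 1 shared factor per lane gave 20 or more calls over the 6 stages in 7 of 100 panels, and 25 or more for D5 vs D1 in 1 of 100. That factor had an SD of 1.38 at every stage, whereas the panel level had an SD of 0.21 at D1 and 1.75 at D5. Each probe was set at its mean over the 18 lanes. These shares therefore do not give the rate of chance calls at the D1 and D5 levels and spreads.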

How the results depend on the processing

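Scaling by EF1A_A or HCFC-1 alone, the reference-class probes tested as well, the 14 numbered lanes without a block, the block on the deposited signal values, those on the lanes of 1 stage pair and the matchings of lanes, lanes left out in sets, the fit of the first run alone and the panel level were chosen after the data were seen; the rest was planned. Causes were not tested unless stated. In simulated panels set at each probe's mean over the 18 embryo lanes, 4-fold changes were recovered at 4% with the dispersion of these lanes and at 96% with 0.1. At that level the spread between lanes limited the recovery more than counting did. Most probes called for D5 vs D1 had lower counts at D1, where the simulation cannot rank the 2 sources. Of the 38 probes, the 20 changed over the 6 stages became 6 with TMM, 9 with DESeq2 size factors, 0 with the negative control mean subtracted, 8 with limma, 13 with limma on the deposited signal values, 0 without the 3 lanes with the fewest EF1A_A counts and 5 with the reference-class probes tested as well. For D2 vs D1 the 0 became 1 with positive controls only, 10 with TMM, 9 with DESeq2 size factors, 10 with the sum of the target probes, 7 with the negative control mean subtracted, 2 with DESeq2, 1 in the 14 numbered lanes, 8 with only the 2 stages compared, 4 without D2.5 replicate 3 and D3 replicate 3, 1 with EF1A_A alone, 1 with the reference-class probes and 1 in the first run alone. D2.5 vs D2 went from 0 to 1 with the sum of the target probes and to 1 with the reference-class probes, and D5 vs D4 from 0 to 1 with DESeq2. For D5 vs D1 the 25 became 12 with TMM, 15 with limma and 0 in the 14 numbered lanes, which hold 1 D5 lane. The split of rises and falls was 27 and 1 with positive controls only, 2 and 10 with TMM, 7 and 10 with DESeq2 size factors, 19 and 2 with the sum of the target probes, 27 and 0 with EF1A_A alone, and 19 and 0 with HCFC-1 alone, which gave 19 over the 6 stages. TMM, DESeq2 size factors and the sum are set by the target probes themselves, so they cannot decide whether the panel as a whole rose. The fry p of 0.0374 became 0.119 with TMM.

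Over all stages, replicate numbers did not pair the lanes: 5 of 19 pairs with 1 number had a correlation of deviations over 0.1 (−0.68 to 0.79), and 4 of 14 lanes correlated best with their own number. With the replicate block, on the 14 numbered lanes, the calls were 5 over the 6 stages, 1 for D2 vs D1 and 0 for D5 vs D1, and the fry p was 0.498. The same lanes without a block gave 22, 1 and 0, so the fall to 5 came with the block and the loss for D5 vs D1 with the 4 lanes left out. On the deposited signal values of all 18 lanes, limma called 16 over the 6 stages and 26 for D5 vs D1 with the block, against 13 and 19 without. D2.5 with D3 was 1 of 6 stage pairs to meet the rule for pairs. With the replicate block on those lanes alone, D3 vs D2.5 went from 0 to 35. Of 30 matchings that cross the numbers of a stage pair, 4 also had all 3 correlations over 0.1, and with the block they gave 33 (D2.5 and D3), 32 (D2 and D3), 8 (D1 and D2) and 5 (D1 and D2.5) calls, so the pairing stays open. Blocked on their own numbers, the D1 and D2 lanes, of which 1 of 3 pairs met the limit, gave 12 calls for D2 vs D1 (11 rises, 1 fall), and the D2 and D2.5 lanes gave 0 (0 at an unadjusted p under 0.05 in edgeR).

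Leaving out each lane in turn gave 0 to 29 calls over the 6 stages (0 without D1 replicate 1 or 3, 4 without D1 replicate 2), 13 to 28 for D5 vs D1 (14 without D1 replicate 1, 13 without D1 replicate 3, 16 without D5 lane a), 0 to 1 for D2 vs D1 (1 without D2.5 replicate 3, D3 replicate 3 or D5 replicate 1), 0 to 2 for D3 vs D2.5 (2 without D2.5 replicate 3), and 0 for D2.5 vs D2, D4 vs D3 and D5 vs D4. The fry p lay between 0.00787 and 0.123, ending the call without D1 replicate 1, 2 or 3 (0.0712, 0.0630, 0.0797) or D5 lane a or b (0.123, 0.121). The testes count stayed at 38.

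The log2 fold change from D1 to D5 changed sign for comp292169 (−1.06 with TMM, −0.80 with DESeq2 size factors, −0.29 in the 14 numbered lanes), comp292635 (−4.35, −4.12, −1.81 with the sum of the target probes, −0.24 with positive controls only, −0.16 with limma, −0.090 on the deposited signal values with or without the block, −3.17 with the replicate block, −3.45 in the 14 numbered lanes, −0.43 without the 3 lanes with the fewest EF1A_A counts), WNT-5a (−0.0099 with TMM, −0.29 in the 14 numbered lanes), FAT3 (−3.31 and −3.06, −1.43 with the sum of the target probes, −0.97 with the replicate block, −1.36 in the 14 numbered lanes), comp287546 (−2.21 and −1.92, −0.37 with the sum of the target probes), comp293586 (−2.06 and −1.87, −0.80 with the sum of the target probes) and comp280581 (−1.35 and −1.18), where the first 2 values of a probe with no setting named are TMM and DESeq2 size factors. Leaving out single lanes gave −0.43 to 0.92 for comp292635 (−0.43 and −0.043 without D1 replicate 2 and 3, −0.39 and −0.28 without D5 lane a and b) and −0.057 to 1.08 for FAT3 (−0.057 without D5 lane a). Of the values of named probes under all alternatives, 33 changed sign, 263 kept their side and direction, 53 lost the call and 1 gained it (comp287546, 6.71 with the negative control mean subtracted).

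Target probes above background at D1, D2, D2.5, D4 and D5 numbered 6, 18, 34, 36 and 38 with at least 2 of 3 lanes. The panel level gave a permutation p of 0.0259 with the sum of the target probes and 0.0462 with EF1A_A alone, and between 0.0935 and 0.244 otherwise. In testes the counts above and below were 0 and 5 with TMM, 0 and 6 with DESeq2 size factors and 0 and 5 with the sum of the target probes, 41 and 1 at 2-fold, and 21 and 0 in an edgeR test of the summed testes lanes, which is 1 sample assumed to vary like the embryo stages. Ratios of testes to the highest stage with TMM were 0.243 for HFM1, 0.163 for comp287546, 0.557 for comp293073_4, 0.258 for comp279056, 0.0709 for myosin-7B, 0.205 for comp289786, 0.466 for comp290695, 0.221 for comp274039 and 0.157 for comp30676. In the same order, with comp293931 (0.928) added, DESeq2 size factors gave 0.165, 0.111, 0.378, 0.175, 0.0481, 0.115, 0.316, 0.150 and 0.107. The sum of the target probes gave 0.754 for HFM1, 0.505 for comp287546, 0.799 for comp279056, 0.220 for myosin-7B, 0.670 for comp289786, 0.684 for comp274039 and 0.487 for comp30676. For comp293586 the ratio to the lowest stage was 3.25 with the deposited signal values. Another 36 testes ratios moved by more than the spread of the testes lanes and 47 did not.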

Other observations

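All tests in this part, and the probes they use, were chosen after the data were seen. Target transcripts abundant in testes were mostly the more abundant ones in embryos. Over the 43 target probes the summed embryo counts and the testes counts had a Spearman rho of 0.68 across probes (Pearson 0.65 on the log2 scale), and 0.81 over the 37 with at least 1000 testes counts. Probes are not independent replicates, and a yield of each probe shared by both tissues was not separated from abundance. In raw counts comp293586 and comp292635_9, the aminotransferase and 1 of the SYCP1 probes, were the only target probes with an embryo lane above the testes mean. Relative to the panel median of 0.553% of the testes count, the summed embryo lanes were high in a trinucleotide repeat-containing gene probe (comp292626, 1.64%) and the MAD2L1-binding protein (1.58%) and low in HFM1 (0.180%).

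The unnumbered lanes of D4 and D5 were higher in target transcripts than the numbered ones. Lanes a and b also differed less from each other, with a chi-square per degree of freedom of 2.90 at D4 and 2.73 at D5. Against the numbered lane it was at least 22.8 and 71.9. The labels do not say whether lanes a and b were collected apart. At D4 the panel level was 4.03 in the numbered lane and 7.03 and 5.79 in lanes a and b. At D5 it was 3.49 in the numbered lane and 6.53 and 6.50 in lanes a and b. RPS9 had 1262 scaled counts in the numbered D4 lane and 2089 and 1336 in lanes a and b, and at D5 4123 in the numbered lane and 3292 and 3085 in lanes a and b.

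A hypothesis is that embryos of a lane were ahead or behind in development relative to their stage. RPS9, which rose over the stages, and comp292635_9, which fell, would then move in opposite directions between lanes of 1 stage. Over the 18 lanes, deviations from the stage means had a Pearson r of −0.71 (permutation p = 0.0029 within stages, adjusted p = 0.0058 by Benjamini-Hochberg over 2 relations) and a Spearman rho of −0.73 (permutation p = 0.0035), and −0.68 without D2.5 replicate 3 and D2 replicate 3. That relation depended on the scaling: r was −0.88 with EF1A_A alone and −0.18 with HCFC-1 alone, −0.020 with the sum of the target probes, 0.030 with positive controls only, 0.55 with TMM and 0.50 with DESeq2's size factors. Within runs it was −0.75 in the 12 lanes of D1 to D3 (permutation p = 0.0131, adjusted p = 0.0525 over 4 relations) and −0.53 in the 6 of D4 and D5 (exact permutation p = 0.0833, adjusted p = 0.167). The panel level, whose stage means rose from D1 to D3 on this scaling, had an r of −0.41 with RPS9 (permutation p = 0.208, adjusted p = 0.208; rho −0.31, permutation p = 0.307), and −0.31 without those lanes. It had −0.62 in the lanes of D1 to D3 (permutation p = 0.139, adjusted p = 0.185), where uneven staging would give a positive r, −0.19 there without D2.5 replicate 3, and 0.14 in the lanes of D4 and D5 (exact permutation p = 0.861, adjusted p = 0.861). The r in the lanes of D1 to D3 also depended on the scaling. It was −0.77 with EF1A_A alone, −0.34 with the sum of the target probes, −0.25 with HCFC-1 alone and −0.083 with positive controls only. With TMM and DESeq2's size factors it was 0.67 and 0.51, but there the mean panel level was not higher at D3 than at D1. Uneven staging was therefore not shown and stays open.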
